A study of Mus musculus with 16 samples.

How the data were processed

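Total RNA from 16 cultures of mouse bone marrow-derived dendritic cells was measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per culture. The cultures fall into 4 groups of 4: 290 or 450 mOsm/L, each without or with LPS at 10 ng/mL. Per the labels, RNA was isolated with an RNeasy kit and cDNA was fragmented and labelled with biotin. The values used are the deposited series table, in which each value is the log2 expression of a probe set. Per the submitters' processing notes, the authors made it with RMA, which corrects background, equalises the arrays' distributions by quantiles and summarises probes into probe sets, in the oligo package. Its version, filters and genome build are not given in the sources used here. RMA sets values relative to the other arrays, so a shift of most transcripts in 1 direction would be largely removed, and low signals are compressed, so folds of dim genes are understated. Signals near the top of the scale are compressed too, where the highest value on any array was 14.32.

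The table holds 22549 probe sets. The platform's annotation gives 1 gene symbol for 20646 of them, several for 551 and none for 1352. By Entrez identifier 20596 were found in a RefSeq gene table, which changed 0 symbols. A probe set was kept when at least 4 arrays exceeded the median of all values, 6.83, which 12097 did. Each gene was represented by its single-gene probe set with the highest mean, which left 10236 genes, and 506 genes had more than 1 probe set to choose from. Close relatives in gene families can share probes, so values of Rnase2a, Ly6i, Ifitm6 and Hspa1a may include similar transcripts. The number of arrays limits the precision.

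Differences were tested with limma 3.58.1 in R 4.3.3: 1 linear model with a mean for each of the 4 groups (12 residual degrees of freedom, 5.53 prior degrees of freedom) and contrasts for salt without LPS, salt with LPS, LPS at 290 mOsm, LPS at 450 mOsm and their interaction. Adjusted p-values are Benjamini-Hochberg values over the genes of a contrast, with a threshold of 0.05. All tests were two-sided. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. There were 25 lists for pathways and 12 for cell types, of which 6 had the minimum of 5 tested genes. Camera was also run with a correlation estimated from the data. Both adjusted p-values are given. Figures were drawn with matplotlib.

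Choices made before the data were examined were the model, the lists, the alternatives and the rule for named genes. For each contrast that rule takes the 8 highest and 8 lowest called log2 changes with the same sign in all 4 mice, leaving out predicted, clone-based, small RNA, olfactory and vomeronasal receptor symbols, any symbol starting with Rn, and probe sets naming several genes, up to 4 members with the smallest adjusted p from each called list, in its direction, and a fixed set of osmotic, TLR4, cytokine and antigen presentation genes. The text names part of these. Of the fixed set, Akr1b3, Hspa1b and H2-K1 are not analysed here, and Ifnb1 was below the filter with values from 5.43 to 6.17.

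Replicate numbers pair the samples, because the labels give the same mouse identifier to arrays of 1 number in each group. Deviations from the group means correlated between arrays of a mouse with r from -0.146 to 0.433 across genes (median 0.0953 over 24 pairs, 11 of them over 0.1), against a median of -0.0351 for different mice. In 12 of the 24 pairs the partner from the same mouse had the highest correlation. Pairs of 1 mouse at the same osmolarity had r from 0.095 to 0.433, and pairs at different osmolarities from -0.146 to 0.269. Whether arrays of 1 mouse and osmolarity share a culture up to day 7 was not tested. The salt effects with and without LPS may therefore not be independent. The fit with the mouse as a replicate block was run as an alternative, as was the mouse as a random term.

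Other alternatives were no filter, a stricter filter at the 65th percentile, the mean of a gene's probe sets, every probe set tested, quantile normalization, cyclic loess, median centring, a trended robust variance, array weights, only the groups compared, fry for the lists, and leaving out each mouse and each array. The model was tested on simulated arrays with 200 changed genes among 10236. For a log2 change of 0.5 it recovered 97% for salt without LPS, 99% for salt with LPS, 99% for LPS at 290 mOsm, 98% for LPS at 450 mOsm and 84% for the interaction. For a change of 1 it recovered 100% in each. False calls were 2.96%, 6.57%, 5.69%, 2.94% and 6.60% of calls, in the same order. With the interferon-stimulated list shifted by 0.3 for salt without LPS, camera called that list and 1 of the other 24. The simulated genes varied independently of each other, while the correlation estimated for this list in the data was 0.57. The simulation therefore does not test calls on genes that vary together.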

Results

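Transcript levels were measured on 16 microarrays of dendritic cells grown from the bone marrow of C57BL/6 mice with GM-CSF at 10 ng/mL, a cytokine that drives marrow precursors towards myeloid cells. Cells were raised in normal medium at 290 mOsm/L, or in medium brought to 450 mOsm/L with NaCl from day 3. On day 7 they were collected and plated for 6 h more, without LPS or with 10 ng/mL of it. LPS is a bacterial cell wall component sensed by the receptor Tlr4. The groups were 290 mOsm, 450 mOsm, 290 mOsm with LPS and 450 mOsm with LPS, with 4 arrays in each. Per the labels, the same 4 mice gave cells to every group, so the replicates are separate animals. Array medians lay between 6.78 and 6.93 on the log2 scale, and 10236 genes were tested. Among pairs of arrays of a group, the SD of the difference over the tested genes was 0.128 to 0.223, against 0.341 to 0.942 between groups. The 450 mOsm replicate 4 array had the lowest median correlation with its own group, r = 0.990 across the tested genes. Changes are given as log2 fold changes with limma's standard error, from 4 mice per group, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05.

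The first comparison asked what salt did to the resting cells. At 450 mOsm the betaine transporter gene Slc6a12 rose 10.4-fold (log2 3.38 ± 0.07) and the inositol transporter gene Slc5a3 rose 5.55-fold (2.47 ± 0.09); both proteins import organic osmolytes. Fxyd2, a regulatory subunit of the sodium pump, rose 9.91-fold (3.31 ± 0.07). Genes typical of neutrophils fell most: the granule gene Ngp was 65.2-fold lower (-6.03 ± 0.18), S100a9 34.8-fold lower (-5.12 ± 0.18) and the lactoferrin gene Ltf 30.6-fold lower (-4.94 ± 0.13). The means of Ngp (6.27) and Ltf (6.17) at 450 mOsm lay below the filter level of 6.83, so their folds rest on dim values. Of 35 interferon-stimulated genes 33 rose, with Rtp4 at 1.79 ± 0.11 and Usp18 at 1.48 ± 0.09 (adjusted p = 7.29e-20, and adjusted p = 0.26 with an estimated correlation). In all, 4530 genes were called, 2104 higher and 2426 lower, of which 90 rose and 114 fell at least 2-fold.

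Among the other large rises without LPS were the chemokine gene Ccl17 (log2 3.11 ± 0.30), the retinoic acid-producing enzyme gene Aldh1a2 (3.01 ± 0.17), the matrix proteoglycan gene Vcan (2.72 ± 0.14), Ly6i (2.93 ± 0.17) and Ifitm6 (2.67 ± 0.12). Rnase2a, which was singled out after its values were seen, rose by 4.65 ± 0.37. At 290 mOsm the means of Rnase2a (6.71), Ly6i (6.49) and Aldh1a2 (6.82) lay below the filter level of 6.83, so their rises are from dim values. Rnase2a belongs, like Ly6i and Ifitm6, to a family of similar genes whose transcripts can share probes. Tnf fell by 1.01 ± 0.14 and the mannose receptor gene Mrc1 by 0.62 ± 0.05. Of the 43 genes named for this comparison, 41 were called by limma, with adjusted p at most 0.000195, and each of the 41 moved the same way in 4 of 4 mice. The exceptions were Nfat5, which encodes the main transcription factor of the osmotic response (-0.03 ± 0.09, adjusted p = 0.799), and the taurine transporter gene Slc6a6 (0.11 ± 0.04, adjusted p = 0.0529). Slc6a6 was higher in 4 of 4 mice and passed in 7 alternatives, among them the replicate block as a random term, quantile normalization and cyclic loess. Apart from the fixed set, the naming rule takes called genes, and the extreme ones only with 1 sign in 4 mice. Such counts of named genes, here and in the comparisons below, are therefore largely set by the rule and lend no separate support.

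Of 25 gene lists fixed beforehand, camera called 9 without LPS, and 0 with a correlation estimated from the data. In the osmoadaptation list, 8 of 14 genes rose and 2 fell (9 and 2 adjusted over the list alone). Its adjusted p was 0.00126, and adjusted p = 0.07 with an estimated correlation. Besides the transporters above, it held the amino acid transporter genes Slc6a9 (1.22 ± 0.10) and Slc38a2 (0.90 ± 0.06). For the interferon-stimulated genes, 33 rose and 0 fell, also when adjusted over the list alone, with a median of 0.67 (adjusted p = 0.26 with an estimated correlation). Further examples were Oasl2 (1.41 ± 0.10), Ifit1 (1.43 ± 0.10) and the interferon regulator gene Irf7 (1.04 ± 0.10). Among type I interferon and TRIF-dependent genes, 5 of 14 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00409, and adjusted p = 0.28 with an estimated correlation). The TLR4 pathway list had 9 of 19 genes higher and 2 lower, and the same counts adjusted over the list alone (adjusted p = 0.0175, and adjusted p = 0.41 with an estimated correlation). Cd14 rose by 0.96 ± 0.06, Ticam2 by 0.59 ± 0.06 and Tlr4 by 0.51 ± 0.08. The type I interferon list shares genes such as Ifit1, Irf7 and Rsad2 with the interferon-stimulated list, and the TLR4 pathway list also holds Irf7. Their calls are therefore not independent, in this and the other comparisons.

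For MHC class I presentation, 12 of 25 genes rose and 2 fell without LPS (13 and 4 adjusted over the list alone), with Nlrc5 at 0.93 ± 0.07 and the peptide transporter gene Tap1 at 0.46 ± 0.08 (adjusted p = 0.0201, and adjusted p = 0.45 with an estimated correlation). In sterol and fatty acid synthesis, 10 of 23 rose and 2 fell, also adjusted over the list alone, among them the fatty acid synthesis genes Scd1 (1.80 ± 0.18), Elovl6 (0.74 ± 0.11) and Fasn (0.67 ± 0.08) and the sterol synthesis gene Mvd (0.47 ± 0.08). Its adjusted p was 0.0133, and adjusted p = 0.81 with an estimated correlation. Of 28 cell cycle genes, 10 rose and 1 fell, also adjusted over the list alone, with Aurkb at 0.70 ± 0.08 and Plk1 at 0.43 ± 0.07 (adjusted p = 0.0201, and adjusted p = 0.81 with an estimated correlation). The call was lost without replicate 2 (adjusted p = 0.131), and without the 450 mOsm replicate 1 (adjusted p = 0.0742) or replicate 2 array (adjusted p = 0.0751). It was also lost with no filter (adjusted p = 0.0826), the stricter filter (0.0653), cyclic loess (0.0937) and fry (0.0687), and with no filter the TLR4 pathway (0.0525) and MHC class I presentation (0.0832) were lost too. Among ribosome biogenesis and MYC target genes, 0 of 19 rose and 13 fell (1 and 15 adjusted over the list alone), with Nop58 at -0.88 ± 0.10, Myc at -0.83 ± 0.10 and Ncl at -0.65 ± 0.07 (adjusted p = 9.83e-05, and adjusted p = 0.28 with an estimated correlation). For cytoskeleton, adhesion and migration, 2 of 21 rose and 13 fell (3 and 13 adjusted over the list alone), led by the gelatinase gene Mmp9 at -2.80 ± 0.17 (adjusted p = 0.00126, and adjusted p = 0.066 with an estimated correlation). The other 16 lists had adjusted p between 0.188 and 0.962.

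Markers of other cell types moved with salt as well. Of 16 neutrophil markers, 0 rose and 15 fell, also adjusted over the list alone, with a median of -2.61 and with S100a8 at -4.54 ± 0.15, Lcn2 at -4.31 ± 0.15 and Ly6g at -3.23 ± 0.17 (adjusted p = 4.12e-16, and adjusted p = 0.0097 with an estimated correlation). All 6 tested mast cell and basophil markers fell, also adjusted over the list alone, with a median of -1.13, among them Cpa3 (-2.01 ± 0.25) and Mcpt8 (-2.03 ± 0.26). The means of Ly6g (4.87), Cpa3 (5.40) and Mcpt8 (5.46) at 450 mOsm lay below 6.83. That list had adjusted p = 0.000371, and adjusted p = 0.14 with an estimated correlation. Dendritic cell markers had 4 of 14 higher and 2 lower, with a median of 0.06 (adjusted p = 0.11). The plasmacytoid dendritic cell list had 3 of 6 higher and 0 lower (adjusted p = 0.0588), and passed in the paired fit with the replicate block (adjusted p = 0.0364). These shifts run alongside every gene group called for this comparison. Median centring of the arrays gave 1335 genes higher and 3047 lower. No filter (3046 and 2381), quantile normalization (2277 and 2162) and cyclic loess (2201 and 2189) gave more rises than falls, so the balance of directions rests on the filter and the scaling. Without the 450 mOsm replicate 4 array, 3812 genes were called.

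**Figure D1:**
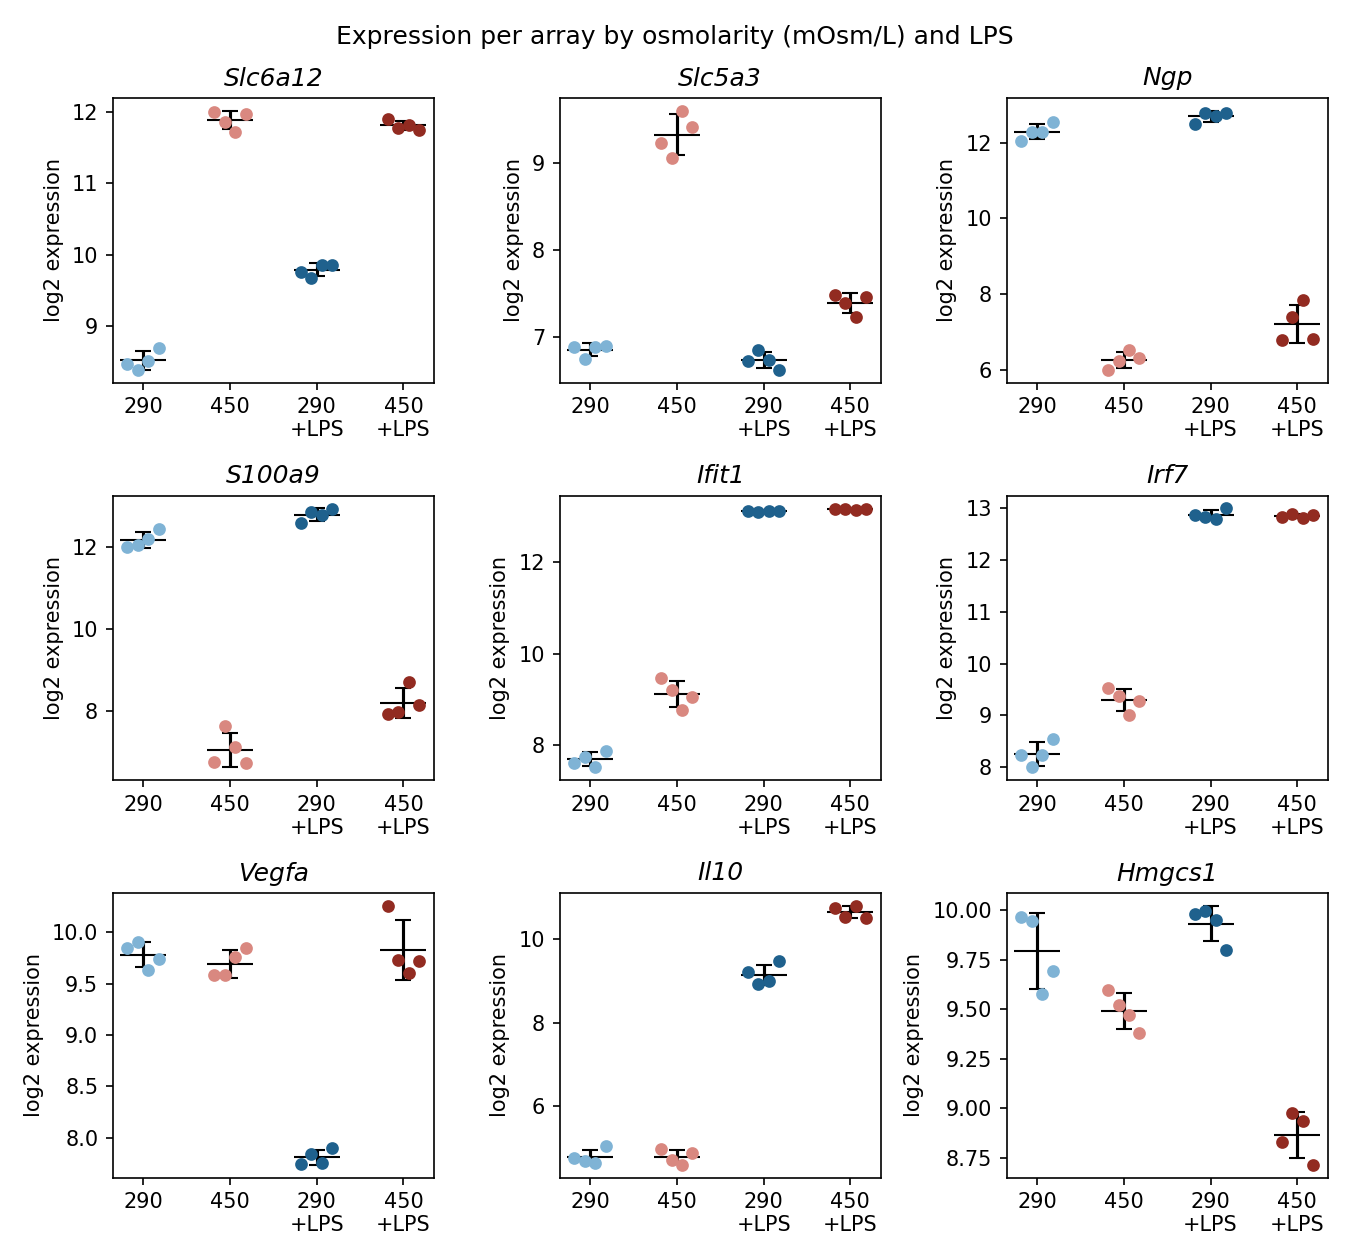
Each panel plots the log2 expression of 1 gene in the 16 arrays, by osmolarity in mOsm/L and LPS; points are the 4 mice, dashes group means and bars the SD. Slc6a12 lay at 8.51 on average at 290 mOsm and at 11.89 at 450 mOsm, while Ngp fell by 6.03 on the log2 scale.

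The second comparison asked what salt did in cells that had received LPS. The lymphocyte activation receptor gene Slamf1 rose 6.50-fold (log2 2.70 ± 0.12), the alarmin cytokine gene Il33 rose 6.41-fold (2.68 ± 0.20) and Hamp, which encodes the iron-regulating peptide hepcidin, rose 6.39-fold (2.68 ± 0.20). Of 20 genes of glycolysis and the hypoxia response 18 rose, among them Vegfa by 2.02 ± 0.11, the mitophagy gene Bnip3 by 1.49 ± 0.10 and the lactate exporter gene Slc16a3 by 1.22 ± 0.08 (adjusted p = 7.67e-16, and adjusted p = 0.093 with an estimated correlation). Neutrophil genes were again lower, with Ngp 44.9-fold (-5.49 ± 0.18) and S100a9 24.2-fold (-4.59 ± 0.18) below 290 mOsm with LPS. Il10, an anti-inflammatory cytokine gene, rose 2.84-fold (1.5 ± 0.12). The mean of Il33 at 290 mOsm with LPS (6.79) lay below the filter level of 6.83. In all, 3956 genes were called, 1724 higher and 2232 lower, of which 91 rose and 107 fell at least 2-fold.

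Salt with LPS also raised Fxyd2 (log2 2.62 ± 0.07), the costimulatory receptor gene Tnfrsf9 (2.37 ± 0.13), the metallothionein gene Mt2 (2.19 ± 0.10), the lipid droplet gene Hilpda (2.12 ± 0.10) and Slc6a12 (2.03 ± 0.07). Nfat5 rose here by 0.64 ± 0.09 and Slc5a3 by 0.65 ± 0.09. The costimulatory genes Cd80 (0.79 ± 0.06) and Cd86 (0.55 ± 0.12) rose with Il6 (0.47 ± 0.08), while Cd40 fell by 0.27 ± 0.07 and Tlr4 by 0.41 ± 0.08. Tnf (-0.18 ± 0.14, adjusted p = 0.335 in limma) and Cxcl10 (-0.27 ± 0.17, adjusted p = 0.213 in limma) did not pass. The means of Cxcl10 (13.37 at 290 mOsm with LPS and 13.1 at 450 mOsm with LPS) lay near the top of the scale, where a difference can be compressed. Rnase2a, again outside the naming rule and chosen after its values were seen, rose by 4.48 ± 0.37. The means of Rnase2a (6.41) and Slc5a3 (6.74) at 290 mOsm with LPS lay below 6.83. Of 41 genes named, 39 were called by limma, with adjusted p at most 0.00421, and all 39 kept 1 direction in 4 of 4 mice.

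Camera called 3 of the 25 lists for salt with LPS, and 0 with an estimated correlation. In the osmoadaptation list, 9 of 14 genes rose and 0 fell, also adjusted over the list alone (adjusted p = 0.000257, and adjusted p = 0.057 with an estimated correlation). The glucose transporter gene Slc2a1, which this list shares with the hypoxia response, rose by 1.17 ± 0.10. Of 20 glycolysis and hypoxia genes, 18 rose and 0 fell, also adjusted over the list alone, with a median of 0.90. The phosphofructokinase gene Pfkl was at 0.93 ± 0.07, and the list had adjusted p = 7.67e-16, and adjusted p = 0.093 with an estimated correlation. In sterol and fatty acid synthesis, 2 of 23 rose and 13 fell, also adjusted over the list alone, with the cholesterol pathway genes Hmgcs1 (-1.07 ± 0.08), Msmo1 (-0.78 ± 0.09) and Insig1 (-0.74 ± 0.11) lower, while Scd1, named beside its value without LPS, was higher (1.77 ± 0.18). Its adjusted p was 0.0253, and adjusted p = 0.91 with an estimated correlation. The interferon-stimulated list, with 1 of 35 higher and 5 lower, did not pass (median -0.07, adjusted p = 0.456). The other lists not called brought the total to 22, with adjusted p from 0.11 to 0.966.

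With LPS, 13 of 16 neutrophil markers fell and 0 rose, also adjusted over the list alone, with a median of -1.71, and Ltf (-4.54 ± 0.13) and Camp (-3.49 ± 0.11) among them (adjusted p = 9.05e-13, and adjusted p = 0.023 with an estimated correlation). Of 14 macrophage markers, 2 rose and 8 fell, also adjusted over the list alone, with Marco at -1.33 ± 0.10, Mertk at -1.12 ± 0.06, Mrc1 at -0.72 ± 0.05 and Adgre1 at -0.68 ± 0.07 (adjusted p = 0.0061, and adjusted p = 0.22 with an estimated correlation). Monocyte markers had 1 of 8 higher and 4 lower, also adjusted over the list alone, with Chil3 at -2.23 ± 0.16, Plac8 at -1.90 ± 0.16 and Ccr2 at -0.94 ± 0.16 (adjusted p = 0.0296, and adjusted p = 0.33 with an estimated correlation). Without LPS that list did not pass, with 3 of 8 higher, 3 lower and a median of 0.30 (camera adjusted p = 0.553). There its member Vcan rose by 2.72 ± 0.14, while the mean of Chil3 was 11.11 at 290 mOsm and 8.99 at 450 mOsm. Mast cell and basophil markers had 1 of 6 higher and 3 lower (1 and 4 adjusted over the list alone), with Mcpt8 at -2.75 ± 0.26 and Cpa3 at -2.39 ± 0.25. The means of Ltf (6.53), Mcpt8 (5.54) and Cpa3 (5.94) at 450 mOsm with LPS lay below 6.83. The mast cell list had adjusted p = 0.0296, and adjusted p = 0.33 with an estimated correlation, and the monocyte and mast cell calls were lost without replicate 4 (adjusted p = 0.0517) and without replicate 3 (adjusted p = 0.0843), respectively. The sterol call was lost without replicate 3 too (adjusted p = 0.0639), and without the 290 mOsm with LPS replicate 2 (adjusted p = 0.0516) or replicate 3 array alone (adjusted p = 0.055), and with the stricter filter (0.0939) and median centring (0.0556). The monocyte call was also lost when only the groups compared were fitted (adjusted p = 0.0523). Across the 10236 genes, the salt effects with and without LPS had Pearson's r = 0.573 and Spearman's rho = 0.505, where genes are not independent replicates. Both comparisons called 796 genes higher (354.4 for independent lists of these sizes) and 1176 lower (529), and 302 in opposite directions.

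**Figure D2:**
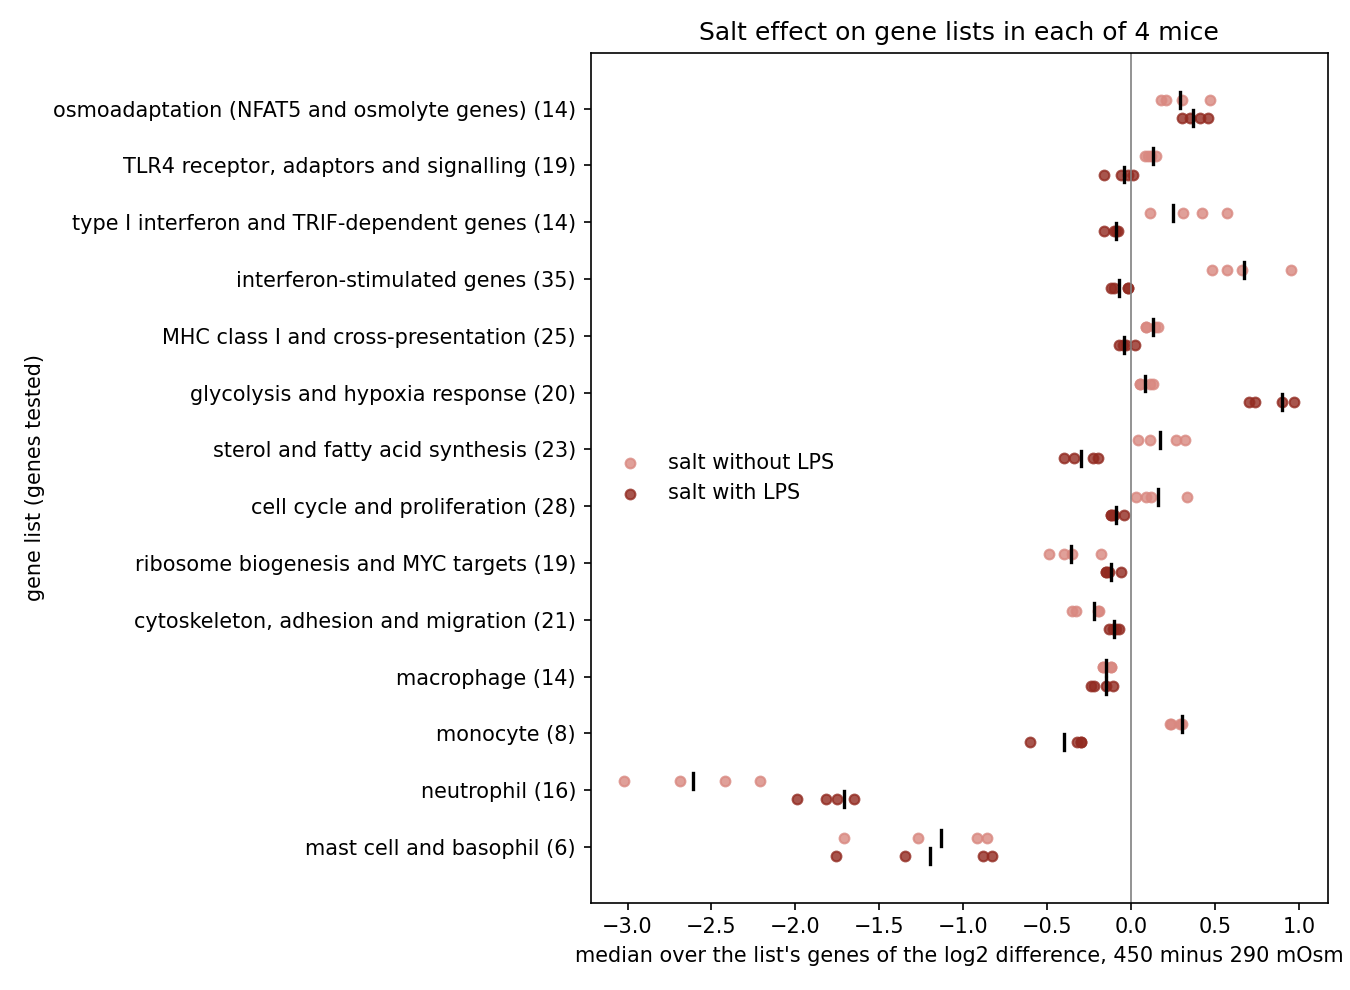
For each gene list called in a salt comparison (tested genes in brackets), points give the median log2 difference between 450 and 290 mOsm in each of 4 mice and black ticks the median of the fitted changes, without LPS (pale) and with LPS (dark). Neutrophil markers had medians of -2.61 and -1.71, and interferon-stimulated genes 0.67 and -0.07.

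The third comparison gave the LPS response at normal osmolarity. LPS raised Il6 197-fold (log2 7.62 ± 0.09), the interferon-induced GTPase gene Iigp1 99.6-fold (6.64 ± 0.12), the chemokine gene Cxcl10 86.3-fold (6.43 ± 0.17) and Nos2, which encodes inducible nitric oxide synthase, 75.8-fold (6.24 ± 0.10). Il12b (5.99 ± 0.15), Il1b (4.91 ± 0.17), Il10 (4.39 ± 0.12) and Tnf (2.21 ± 0.14) rose as well. The phosphatidate phosphatase gene Lpin1 fell 9-fold (-3.17 ± 0.12), the potassium channel gene Kcnj2 7.33-fold (-2.87 ± 0.13) and the stress gene Sesn1 7.16-fold (-2.84 ± 0.08). Without LPS the means of Il6 (4.26), Iigp1 (4.53), Nos2 (6.26), Il12b (6.73) and Il10 (4.76) lay below the filter level of 6.83, as did those of Lpin1 (6.08) and Kcnj2 (6.43) with LPS, so their folds rest on dim values. In all, 7521 genes were called, 2702 higher and 4819 lower, of which 752 rose and 569 fell at least 2-fold. The median over all genes was -0.113. Cyclic loess removed that shift and gave 3857 higher and 3736 lower, so small falls near that median are relative to it.

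Camera called 13 lists at 290 mOsm. All 35 interferon-stimulated genes rose, also adjusted over the list alone, with a median of 3.42, including Cmpk2 (5.54 ± 0.10), Ifit1 (5.42 ± 0.10), Rsad2 (4.84 ± 0.09), Irf7 (4.62 ± 0.10) and Isg20 (4.61 ± 0.07), beside Gbp5 (6.17 ± 0.09), Cxcl9 (5.71 ± 0.08) and the activation marker gene Cd69 (6.05 ± 0.17), which are outside it and had means below 6.83 without LPS (6.34, 5.62 and 6.08). The interferon-stimulated list had adjusted p = 3.25e-28, and adjusted p = 0.066 with an estimated correlation. Of 18 proinflammatory cytokine genes, 18 rose (median 2.93, adjusted p = 1.91e-13, and adjusted p = 0.019 with an estimated correlation). Of 14 type I interferon and TRIF-dependent genes, 13 rose and 0 fell (median 4.82, adjusted p = 1.85e-12, and adjusted p = 0.015 with an estimated correlation). Among 19 chemokine genes, 18 rose and 1 fell (adjusted p = 4.97e-11, and adjusted p = 0.044 with an estimated correlation). Of 18 costimulation and maturation genes, 18 rose, with Cd40 at 5.31 ± 0.07, Il15 at 3.47 ± 0.10, Cd86 at 2.33 ± 0.12 and Cd80 at 2.03 ± 0.06 (adjusted p = 2.29e-12, and adjusted p = 0.023 with an estimated correlation). Of 18 NF-kB target genes, 18 rose, with Nfkbiz at 3.06 ± 0.10 and Traf1 at 2.99 ± 0.06 (adjusted p = 1.85e-12, and adjusted p = 0.072 with an estimated correlation). These counts were the same adjusted over the list alone.

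Among TLR4 pathway genes, 14 of 19 rose and 4 fell with LPS at 290 mOsm, with Myd88 at 1.39 ± 0.07 and Tlr4 itself at -0.41 ± 0.08 (adjusted p = 0.000128, and adjusted p = 0.072 with an estimated correlation). Anti-inflammatory regulators had 13 of 18 higher and 3 lower, led by Il10 and the cytokine signalling suppressor gene Socs3 (3.91 ± 0.08), with adjusted p = 2.3e-05, and adjusted p = 0.072 with an estimated correlation. MHC class I presentation had 17 of 25 higher and 7 lower, with Nlrc5 at 3.21 ± 0.07 and Tap1 at 2.87 ± 0.08 (adjusted p = 2.79e-05, and adjusted p = 0.072 with an estimated correlation). Falls prevailed in 4 of the called lists. Of 20 lysosomal genes, 3 rose and 17 fell, with the cholesterol exporter gene Npc1 at -0.92 ± 0.06 (adjusted p = 0.0105, and adjusted p = 0.44 with an estimated correlation). Of 28 cell cycle genes, 2 rose and 23 fell, with Rrm1 at -1.01 ± 0.10 (adjusted p = 0.0105, and adjusted p = 0.56 with an estimated correlation). Of 19 ribosome biogenesis and MYC target genes, 1 rose and 16 fell, with Myc at -1.94 ± 0.10 (adjusted p = 0.00291, and adjusted p = 0.33 with an estimated correlation). Of 23 oxidative phosphorylation genes, 3 rose and 18 fell, with Idh3a at -1.01 ± 0.07 (adjusted p = 0.0391, and adjusted p = 0.56 with an estimated correlation). All 7 counts were the same adjusted over the list alone.

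Of the cell type lists at 290 mOsm, the plasmacytoid dendritic cell list passed, with 5 of 6 genes higher and 1 lower, also adjusted over the list alone (adjusted p = 0.0348, and adjusted p = 0.17 with an estimated correlation). It holds the interferon-induced gene Bst2, and it did not pass in the paired fit with the replicate block (adjusted p = 0.0532). It was also lost without the 290 mOsm with LPS replicate 1 array (adjusted p = 0.0503). Oxidative phosphorylation was lost without replicate 2 (adjusted p = 0.0575) and without the 290 mOsm replicate 1 array (adjusted p = 0.0511), and with the stricter filter (0.0672) and every probe set tested (0.0733). The cell cycle call was lost with the stricter filter (adjusted p = 0.118), and the plasmacytoid call with quantile normalization (0.0573) and cyclic loess (0.144). Among the genes that fell were Mrc1 (-0.78 ± 0.05) and the desaturase gene Scd2 (-2.80 ± 0.17). The other 12 lists had adjusted p between 0.0712 and 0.971, and all 36 genes named were called by limma in 1 direction in 4 of 4 mice (adjusted p at most 0.000226).

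The fourth comparison gave the LPS response of cells raised at 450 mOsm. Il6 rose 218-fold (log2 7.77 ± 0.09), Il12b 103-fold (6.69 ± 0.15), Nos2 90.6-fold (6.50 ± 0.10) and the oxysterol-producing gene Ch25h 60.4-fold (5.92 ± 0.16). Cxcl10 (5.90 ± 0.17), Il10 (5.88 ± 0.12), Iigp1 (5.58 ± 0.12), Ifit1 (4.03 ± 0.10) and Cd80 (3.10 ± 0.06) rose too. The chemokine receptor gene Ccr2 fell 14.2-fold (-3.82 ± 0.16), Tmem154 13.3-fold (-3.74 ± 0.09), Cd28 11.3-fold (-3.50 ± 0.11) and Lpin1 10.6-fold (-3.40 ± 0.12). The folds of Il6 (mean 4.60 without LPS), Il12b (6.35), Nos2 (6.74), Ch25h (6.15), Il10 (4.78) and Iigp1 (5.38), and of Tmem154 (mean 6.72 with LPS), Cd28 (6.28) and Lpin1 (6.12), rest on dim values below the filter level of 6.83. In all, 7348 genes were called, 2707 higher and 4641 lower, of which 767 rose and 617 fell at least 2-fold. Cyclic loess gave 3722 higher and 3660 lower.

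Camera called 17 lists at 450 mOsm, and 4 with an estimated correlation. Of 18 proinflammatory cytokine genes 18 rose (median 3.41, adjusted p = 3.04e-14, and adjusted p = 0.015 with an estimated correlation), and of 35 interferon-stimulated genes 35 rose (median 2.62, adjusted p = 1.74e-24, and adjusted p = 0.08 with an estimated correlation). Rises were called for 18 of 19 chemokine genes (adjusted p = 2.35e-11, and adjusted p = 0.04 with an estimated correlation), 17 of 18 costimulation and maturation genes (adjusted p = 9.7e-12, and adjusted p = 0.027 with an estimated correlation) and 13 of 14 type I interferon and TRIF-dependent genes (adjusted p = 1.25e-11, and adjusted p = 0.015 with an estimated correlation). All 18 NF-kB target genes rose (adjusted p = 1.61e-12, and adjusted p = 0.084 with an estimated correlation). Anti-inflammatory regulators had 14 of 18 higher and 3 lower (adjusted p = 6.62e-06, and adjusted p = 0.08 with an estimated correlation). The TLR4 pathway had 10 of 19 higher and 3 lower, with Tlr4 at -1.33 ± 0.08 (adjusted p = 0.00365, and adjusted p = 0.19 with an estimated correlation). MHC class I presentation had 13 of 25 higher and 7 lower, with Tap1 at 2.24 ± 0.08 and Nlrc5 at 2.16 ± 0.07 (adjusted p = 0.000779, and adjusted p = 0.18 with an estimated correlation).

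Glycolysis and hypoxia genes had 15 of 20 higher and 2 lower with LPS at 450 mOsm, with Pfkfb3 at 3.26 ± 0.08, Bnip3 at 2.21 ± 0.10, Hk2 at 1.31 ± 0.08 and Hif1a at 1.28 ± 0.08 (adjusted p = 2.04e-06, and adjusted p = 0.19 with an estimated correlation). Of 12 oxidative stress genes, 8 rose and 2 fell, with Sod2 at 1.56 ± 0.10 and the cystine transporter gene Slc7a11 at 1.36 ± 0.11 (adjusted p = 0.00576, and adjusted p = 0.37 with an estimated correlation). Of 11 heat shock genes, 7 rose and 2 fell, with Hspa1a at 1.33 ± 0.07 (adjusted p = 0.0179, and adjusted p = 0.22 with an estimated correlation). In sterol and fatty acid synthesis, 1 of 23 rose and 22 fell, with Scd2 at -2.41 ± 0.17, Dhcr7 at -1.92 ± 0.07 and Fasn at -1.63 ± 0.08 (adjusted p = 0.000591, and adjusted p = 0.37 with an estimated correlation). Of 28 cell cycle genes, 2 rose and 24 fell, with Kif11 (mean 5.98 with LPS) at -1.85 ± 0.09 and Plk1 at -1.42 ± 0.07 (adjusted p = 0.000254, and adjusted p = 0.33 with an estimated correlation). Falls were also called for 17 of 20 lysosomal genes against 2 rises (adjusted p = 0.00332, and adjusted p = 0.32 with an estimated correlation) and for 19 of 23 oxidative phosphorylation genes against 2 (adjusted p = 0.00248, and adjusted p = 0.37 with an estimated correlation). Ribosome biogenesis and MYC targets had 3 of 19 higher and 15 lower (adjusted p = 0.0408, and adjusted p = 0.39 with an estimated correlation), a call lost without the 450 mOsm with LPS replicate 1 array (adjusted p = 0.0511), with the stricter filter (0.0911) and with every probe set tested (0.0687). The heat shock call was lost with quantile normalization (adjusted p = 0.0685). Slc5a3 fell by 1.94 ± 0.09. All 17 counts were the same adjusted over the list alone, the other 8 lists had adjusted p from 0.0671 to 0.977, and camera called 0 of the 6 cell type lists (adjusted p from 0.108 to 0.719). All 29 genes named were called by limma in 1 direction in 4 of 4 mice (adjusted p at most 1.37e-09).

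The last comparison asked whether salt changed the LPS response, as the difference between the LPS effects at 450 and 290 mOsm. Lcn2, which encodes the iron-binding protein lipocalin 2 and is on the neutrophil list, had the largest positive difference (log2 4.16 ± 0.21). Its means were 12.27 at 290 mOsm and 7.96 at 450 mOsm without LPS, and 13.56 and 13.41 with LPS. The difference thus followed its lower level at 450 mOsm without LPS, and both levels with LPS lay near the top of the scale. Chst11 (3.16 ± 0.16), Slamf1 (3.09 ± 0.18), Hilpda (2.82 ± 0.14) and Il33 (2.53 ± 0.28) were among the next positive differences. The most negative were Vcan (-2.72 ± 0.20), Ifitm6 (-2.32 ± 0.17), Ccl17 (-2.11 ± 0.43) and Rtp4 (-1.97 ± 0.15). Without LPS, Slamf1 (5.60 at 290 mOsm, 5.21 at 450 mOsm) and Il33 (4.67 and 4.82) had means below the filter level of 6.83, as Il33 had at 290 mOsm with LPS (6.79), so their differences rest on dim values. Interferon-stimulated genes had a smaller LPS rise at 450 mOsm, and the LPS effect on genes of glycolysis and hypoxia was more positive there. Those lists had adjusted p = 4.53e-25 and 2.77e-13, and each had adjusted p = 0.15 with an estimated correlation. For the interferon-stimulated list the median salt effect was 0.67 without LPS and -0.07 with LPS. Its smaller LPS rise thus followed higher levels at 450 mOsm without LPS. For glycolysis and hypoxia these medians were 0.08 and 0.90. Of the 35 interferon-stimulated genes, 26 had means at or above 11 at 290 mOsm with LPS, where the highest value on any array was 14.32. Over all 10236 genes, however, the LPS effects at the 2 osmolarities were closely related, with Pearson's r = 0.922, Spearman's rho = 0.895 and a slope of 0.997. Within single mice r ran from 0.893 to 0.921. These correlations are across genes, which are not independent replicates. Both LPS comparisons called 2189 genes higher (714.6 for independent lists) and 4135 lower (2185), and 140 in opposite directions.

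The interaction was called for 2161 genes, 1097 positive and 1064 negative, of which 105 and 89 were at least 2-fold. Of these, 710 rose with LPS at both osmolarities and 694 fell at both. Of 35 interferon-stimulated genes, 32 had a negative interaction and 0 a positive (33 and 0 adjusted over the list alone), with a median of -0.80. Usp18 was at -1.41 ± 0.13, Ifit1 at -1.39 ± 0.15 and Irf7 at -1.06 ± 0.14, and the list had adjusted p = 4.53e-25, and adjusted p = 0.15 with an estimated correlation. Of 20 glycolysis and hypoxia genes, 16 were positive and 0 negative (18 and 1 adjusted over the list alone), with a median of 0.79 and with Vegfa at 2.11 ± 0.15, Bnip3 at 1.75 ± 0.15 and Slc2a1 at 1.69 ± 0.14. That list had adjusted p = 2.77e-13, and adjusted p = 0.15 with an estimated correlation.

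Camera called 10 lists for the interaction, and 0 with an estimated correlation. In sterol and fatty acid synthesis, 0 of 23 were positive and 14 negative (15 adjusted over the list alone), with Fasn at -0.91 ± 0.11 and Hmgcs1 at -0.77 ± 0.12 (adjusted p = 2.15e-07, and adjusted p = 0.34 with an estimated correlation). TLR4 pathway genes had 2 of 19 positive and 10 negative, also adjusted over the list alone, with Tlr4 at -0.91 ± 0.12 and Cd14 at -0.68 ± 0.09 (adjusted p = 0.0006, and adjusted p = 0.19 with an estimated correlation). MHC class I presentation had 11 of 25 negative and 0 positive (12 adjusted over the list alone), with Nlrc5 at -1.05 ± 0.10 and Tap1 at -0.64 ± 0.11 (adjusted p = 0.000128, and adjusted p = 0.19 with an estimated correlation). Type I interferon and TRIF-dependent genes had 6 of 14 negative and 0 positive, also adjusted over the list alone, with Cxcl9 at -1.03 ± 0.11 (adjusted p = 8.84e-05, and adjusted p = 0.15 with an estimated correlation). Cell cycle genes had 10 of 28 negative and 1 positive (11 and 1 adjusted over the list alone), with Kif11 at -0.95 ± 0.13 (adjusted p = 0.000261, and adjusted p = 0.42 with an estimated correlation). Ribosome biogenesis and MYC targets had 5 of 19 positive and 0 negative (9 adjusted over the list alone, adjusted p = 0.00607, and adjusted p = 0.42 with an estimated correlation). Slc5a3 had an interaction of -1.82 ± 0.13. Cxcl9 without LPS (5.62 at 290 mOsm, 5.70 at 450 mOsm), Kif11 at 450 mOsm with LPS (5.98) and Slc5a3 at 290 mOsm with LPS (6.74) had means below 6.83.

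Proinflammatory cytokines had 7 of 18 interactions positive and 1 negative, also adjusted over the list alone, and Tnf was at 0.83 ± 0.20, or 0.61 and not passing without replicate 2 (list adjusted p = 0.0468, and adjusted p = 0.42 with an estimated correlation). The means of Tnf were 10.74 at 290 mOsm and 9.73 at 450 mOsm without LPS, and 12.95 and 12.77 with LPS. Its interaction thus followed the lower level at 450 mOsm without LPS. Il6 (0.14 ± 0.12, adjusted p = 0.463 in limma) and Il1b (0.16 ± 0.23, adjusted p = 0.687 in limma) did not pass. With LPS the means of Il1b (13.3 at 290 mOsm and 13.48 at 450 mOsm) lay near the top of the scale, where a difference can be compressed. Anti-inflammatory regulators had 7 of 18 positive and 2 negative (7 and 3 adjusted over the list alone), with the interleukin-1 receptor antagonist gene Il1rn at 1.58 ± 0.10 and Il10 at 1.49 ± 0.16 (adjusted p = 0.0468, and adjusted p = 0.42 with an estimated correlation). That call was lost in the paired fit with the replicate block (adjusted p = 0.0679). The means of Il1rn were 11.77 at 290 mOsm and 10.5 at 450 mOsm without LPS, and 12.68 and 12.98 with LPS. Without LPS the means of Il6 (4.26 and 4.60) and Il10 (4.76 and 4.78) at 290 and 450 mOsm lay below 6.83. Cd80 had an interaction of 1.06 ± 0.09. Of the cell type lists, neutrophil markers had 4 of 16 positive and 1 negative (5 and 1 adjusted over the list alone, adjusted p = 0.0462, and adjusted p = 0.44 with an estimated correlation). Macrophage markers had 1 of 14 positive and 2 negative (1 and 3 adjusted over the list alone, adjusted p = 0.0462, and adjusted p = 0.33 with an estimated correlation), and monocyte markers had 5 of 8 negative and 0 positive (5 and 1 adjusted over the list alone, adjusted p = 0.0101, and adjusted p = 0.30 with an estimated correlation). These calls of proinflammatory, anti-inflammatory, macrophage and neutrophil genes were each lost in several of the fits that left out a mouse or an array, with adjusted p up to 0.156 (without replicate 2), 0.0865 (without the 450 mOsm replicate 3), 0.0978 (without the 290 mOsm replicate 4) and 0.138 (without the 290 mOsm with LPS replicate 1), respectively. Median centring lost these calls too (adjusted p = 0.0622, 0.0523, 0.0559 and 0.0559, in the same order). The mean of a gene's probe sets lost the proinflammatory and the anti-inflammatory call (both adjusted p = 0.0519), array weights the macrophage and the neutrophil call (both 0.065) and the anti-inflammatory call (0.0529), quantile normalization the anti-inflammatory (0.0813) and the neutrophil call (0.07), and the stricter filter (0.0971) and cyclic loess (0.0756) the anti-inflammatory call. Without replicate 2 the count of interaction genes was 1383. The other 15 lists had adjusted p between 0.074 and 0.722, and 28 of the 30 genes named were called by limma in 1 direction in 4 of 4 mice (adjusted p at most 0.00641).

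**Figure D3:**
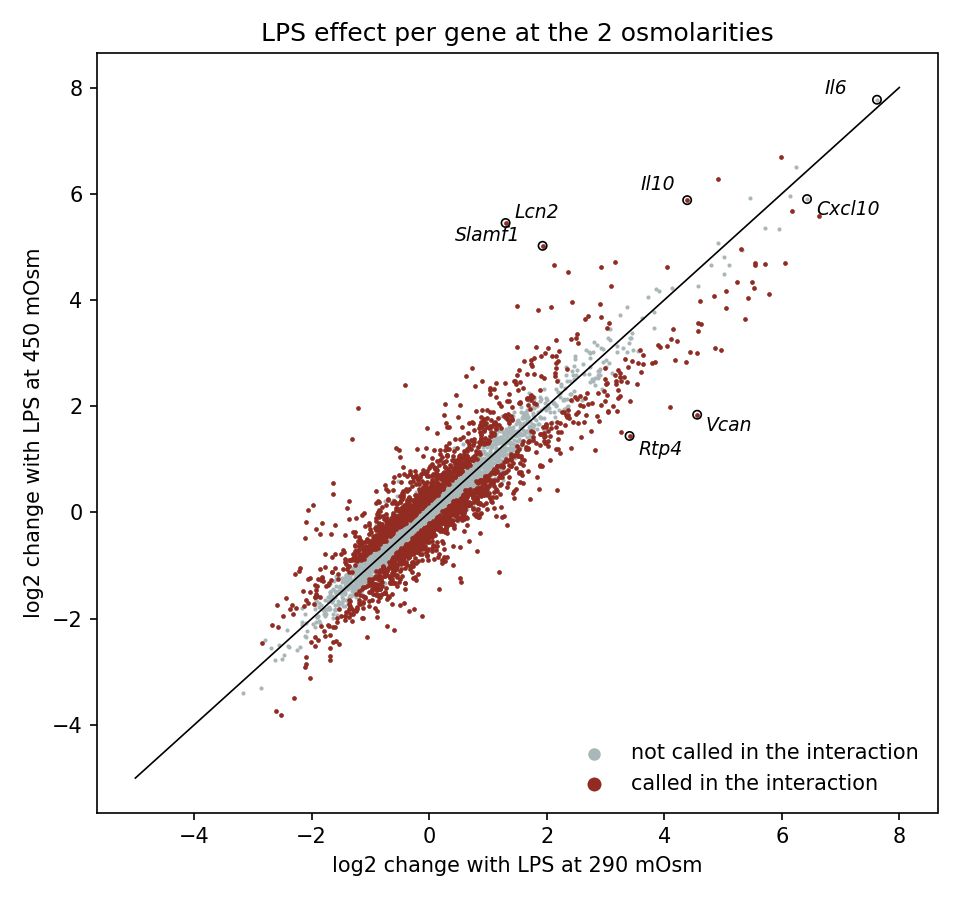
Each point is 1 of the 10236 genes, with its log2 change with LPS at 290 mOsm on the horizontal axis and at 450 mOsm on the vertical axis; dark red marks the 2161 genes called in the interaction and the line marks equal effects. Il6 lies near the line, Lcn2 and Slamf1 above it, and Vcan and Rtp4 below it.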

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

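The splits of the arrays in this part were planned before the data were examined, except those with the salt effect subtracted, which were chosen after the results were seen, as were the tests of the neutrophil, interferon-stimulated and glycolysis patterns.

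Neutrophil markers were lower at 450 mOsm both without and with LPS. A shift carried by 1 mouse or array is argued against by the per-mouse medians over the list, whose highest among 8 was -1.65. These 8 medians come from 4 mice, so they are not 8 independent values. Whether the neutrophil transcripts fell equally, as a smaller share of otherwise unchanged neutrophils would give, cannot be told apart from unequal loss: the SD of the salt effects was 21.8 times the median SE, but over 3 genes bright enough to test, from Lcn2 (-4.31) to Mmp8 (-0.34). Within groups the list's genes varied together. Their mean pairwise correlation was 0.261, against a 95th percentile of 0.0787 among 10000 random lists (percentile 100). Lists that are not cell type markers also varied together: camera's estimated correlation was 0.57 for interferon-stimulated genes and 0.26 for this list. The test therefore cannot tell shared regulation from a share of neutrophils that differs between cultures. Such a share is an undecided candidate explanation. An effect of salt on the development of the cells, which the design names, stays open and was not tested.

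Interferon-stimulated genes were higher at 450 mOsm without LPS (camera adjusted p = 7.29e-20, and adjusted p = 0.26 with an estimated correlation), and the salt effect with LPS did not pass. A ceiling of the array signal is argued against for the 9 members under 11 at 290 mOsm with LPS, where the median salt effect was 0.01 with LPS and 0.52 without. For the 26 members at or above 11 (-0.08 with LPS, 0.71 without), a ceiling and an absent salt effect cannot be told apart, since both give a flat signal. The list's median lay above that of the dendritic cell list by 0.61 (95% bootstrap interval over genes 0.41 to 0.78). The list was picked after camera had called it against other genes, so a gap was largely given beforehand. The gap shows only that a loss of neutrophil RNA did not raise both lists alike. Unequal effects of such a loss were not tested. That interval treats genes as independent, so it may be too narrow, and it leaves out the spread between mice. Per-mouse medians ran from 0.48 to 0.95 for this list and from 0.03 to 0.10 for the dendritic cell list. A single mouse is argued against by the lowest per-mouse median, 0.48. An effect of osmolarity on interferon signalling stays open as an untested hypothesis.

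Glycolysis and hypoxia genes were higher at 450 mOsm with LPS (camera adjusted p = 7.67e-16, and adjusted p = 0.093 with an estimated correlation), where neutrophil (median -1.71), macrophage (-0.15), monocyte (-0.40) and mast cell markers (-1.20) were lower. The lowest of the 4 per-mouse medians was 0.70, which argues against 1 mouse carrying the shift. The list's median exceeded that of the dendritic cell list by 0.82 (95% bootstrap interval over genes 0.38 to 1.09). This list too was picked after camera had called it, so a gap was largely given beforehand. The gap shows only that a loss of neutrophil RNA did not raise both lists alike, and unequal effects were not tested. That interval treats genes as independent, so it may be too narrow, and it leaves out the spread between mice. Per-mouse medians ran from 0.70 to 0.97 for this list and from -0.01 to 0.12 for the dendritic cell list. An osmolarity effect on the response to LPS is a hypothesis that was not tested further, and oxygen levels in the cultures are not given in the sources used here.

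The interaction test found effects of LPS that differed between 290 and 450 mOsm for 2161 genes. The lists in this paragraph were called by camera at its preset correlation, and 0 of them with an estimated correlation. A ceiling of the array signal was left undecided for 26 of the 35 interferon-stimulated genes. The median interaction was -0.80 for interferon-stimulated genes, -0.42 for type I interferon and TRIF-dependent genes, -0.21 for the TLR4 pathway, -0.18 for MHC class I presentation, -0.50 for sterol and fatty acid synthesis and -0.30 for the cell cycle. It was 0.79 for glycolysis and hypoxia, 0.17 for proinflammatory cytokines, 0.23 for anti-inflammatory regulators and 0.23 for ribosome biogenesis and MYC targets. The proinflammatory and anti-inflammatory calls were lost in several fits that left out a mouse or an array, and with median centring. For cell type markers the median interaction was -0.15 for macrophages, -0.63 for monocytes and 0.22 for neutrophils. The macrophage and neutrophil calls were lost without replicate 1, without replicate 3 and with median centring. The LPS effect was more positive at 450 mOsm for Lcn2 (4.16), Chst11 (3.16), Slamf1 (3.09), Hilpda (2.82), Il33 (2.53), Vegfa (2.11), Bnip3 (1.75), Slc2a1 (1.69), Il1rn (1.58), Il10 (1.49), Cd80 (1.06) and Tnf (0.83). It was more negative for Vcan (-2.72), Ifitm6 (-2.32), Ccl17 (-2.11), Rtp4 (-1.97), Slc5a3 (-1.82), Usp18 (-1.41), Ifit1 (-1.39), Irf7 (-1.06), Nlrc5 (-1.05), Cxcl9 (-1.03), Kif11 (-0.95), Tlr4 (-0.91), Fasn (-0.91), Hmgcs1 (-0.77), Cd14 (-0.68) and Tap1 (-0.64). With LPS the means at 290 and 450 mOsm were close for Lcn2 (13.56 and 13.41) and Tnf (12.95 and 12.77). The interactions of Lcn2 and Tnf followed their lower levels at 450 mOsm without LPS. With LPS the means were also close for Vcan (11.66 and 11.66), Usp18 (12.66 and 12.73), Ifit1 (13.12 and 13.16) and Irf7 (12.87 and 12.85). Their negative interactions followed higher levels at 450 mOsm without LPS. Il10 (9.16 and 10.66) and Slamf1 (7.53 and 10.23), in contrast, differed with LPS.

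In 12 of 424 groups of 4 arrays tested for the named genes, 1 array stood far from the other 3, where chance alone gives about 21.2. Without LPS these were Slc5a3 in 290 mOsm replicate 2 (6.75), Il33 in 290 mOsm replicate 1 (4.61), and Lcn2 (7.34) and Npc1 (11.72) in 450 mOsm replicate 4. At 290 mOsm with LPS they were Cd69 (12.33) and Il1b (13.26) in replicate 1, Tlr4 in replicate 2 (9.12), Hilpda in replicate 3 (7.30) and Ly6g in replicate 4 (8.68). At 450 mOsm with LPS they were Rsad2 in replicate 2 (13.66), and Npc1 (10.82) and Socs3 (11.26) in replicate 3. Probe sets that name no gene or several were outside the gene counts, and of 1014 tested with limma, 199 were higher with salt without LPS, 160 with salt with LPS, 190 with LPS at 290 mOsm and 182 with LPS at 450 mOsm, while 64 had a positive interaction.

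In each of the 4 comparisons of groups, 1 of 35 splits of the 8 arrays, the real one, gave as many genes. The share cannot fall below 1 in 35. Every other split also puts the group difference into the spread within groups, which lowers its count. These splits alone therefore do not exclude chance. The real splits, fitted on those 8 arrays, called 3984 genes for salt without LPS, 4142 for salt with LPS, 7585 for LPS at 290 mOsm and 7219 for LPS at 450 mOsm, and the highest other split called 0 in each, also among the 8 splits that part all 4 mice. For the interaction, exchanging osmolarity labels within each LPS state also breaks up the salt effect itself, so the 1 of 100 drawn splits that gave as many genes (2161 in the real split, 1182 in the highest other) decides nothing. The splits were repeated with each gene's mean salt effect over both LPS states subtracted first. Again 1 of 100, the real one, gave as many genes (2161), and the highest other called 0. The interaction itself stays in the data and adds to the spread within relabelled groups. Labels were also exchanged without regard to the mouse. These splits alone therefore do not exclude chance either.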

How the results depend on the processing

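The alternatives were chosen before the data were examined, and where a value changed the cause was not tested unless stated. Counts of genes stayed within 1.5 times the reported count in every alternative for the 4 comparisons of groups. The ranges on leaving out a mouse or an array were 3200 to 4622 for salt without LPS, 2925 to 3810 for salt with LPS, 7049 to 7430 for LPS at 290 mOsm, 6875 to 7379 for LPS at 450 mOsm and 1383 to 2266 for the interaction, with 1383 without replicate 2. The directions shifted with filter and scaling: salt without LPS gave 1335 higher and 3047 lower with median centring, 3046 and 2381 with no filter, 2277 and 2162 with quantile normalization, and 2201 and 2189 with cyclic loess. Cyclic loess gave 3857 and 3736 for LPS at 290 mOsm and 3722 and 3660 at 450 mOsm, as it moved the median of all genes from -0.113 to 0.017 and from -0.093 to 0.027. The correlation of the LPS effects ranged from 0.911 to 0.928 over all alternatives. With a correlation estimated per list, camera called 0 gene lists for salt without LPS, 0 for salt with LPS, 4 for LPS at 290 mOsm, 4 for LPS at 450 mOsm and 0 for the interaction, and of cell type lists 1, 1, 0 and 0 in both salt comparisons, LPS at 290 mOsm and the interaction. With fry, which does not compare a list with other genes, the calls were 10 gene lists for salt with LPS, 23 for LPS at 290 mOsm, and 5 cell type lists for each of salt without LPS, LPS at 290 mOsm and LPS at 450 mOsm. With no filter on dim probe sets, 8 gene lists were called for salt with LPS, and 5 cell type lists for salt without LPS and 8 with LPS. For LPS at 290 mOsm, 0 cell type lists were called with the replicate block, the stricter filter, quantile normalization or cyclic loess, and 0 to 1 when a mouse or an array was left out, with 0 without the 290 mOsm with LPS replicate 1. For the interaction, 1 cell type list was called with median centring and 1 with array weights, and 1 to 4 when a mouse or an array was left out. The replicate block changed no other list call than those given with the lists. Camera could not be run with the mouse as a random term, so list tests with it were not run. The 62 list calls kept their side of the threshold in 1504 values and lost it in 136. Of these, 52 were with an estimated correlation, 52 on leaving out a mouse or an array, and 32 under other settings. Among the other settings, the stricter filter (6), median centring (5) and quantile normalization (4) had the largest numbers. Of named genes, 4485 values kept direction and side of the threshold, 8 newly passed (7 for Slc6a6 without LPS and 1 for Cxcl10 in salt with LPS) and 1 no longer passed (Tnf in the interaction, 0.61 without replicate 2). The sign turned 9 times, in genes that did not pass: Nfat5 in salt without LPS (-0.03) was at 0.01 with quantile normalization, at 0.02 with cyclic loess and between -0.13 and 0.07 when a mouse or an array was left out, and Il1b in the interaction (0.16) was between -0.06 and 0.40. Signal over background limits folds of genes that are dim in a compared group, which the filter kept when 4 arrays exceeded 6.83, such as Il6 at 290 mOsm (mean 4.26) and Ngp at 450 mOsm (mean 6.27).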

Other observations

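The tests of solute carrier genes in this part were chosen before their result was seen, and the genes named here were chosen after their values were seen. Besides the osmolyte transporters, other membrane transporter genes moved with salt. Slc6a20a, which encodes a proline transporter, rose in both salt comparisons (1.55 ± 0.11 without LPS, 1.79 ± 0.11 with LPS), as did the zinc transporter gene Slc39a4 (1.53 ± 0.07 and 1.01 ± 0.07). The iron exporter gene Slc40a1 fell in both (-1.10 ± 0.09 and -1.07 ± 0.09). The nucleoside transporter gene Slc28a2 (1.73 ± 0.13), the metal ion transporter gene Slc39a14 (1.32 ± 0.07), the glutamate transporter gene Slc1a2 (1.31 ± 0.15) and the lactate transporter gene Slc16a1 (1.04 ± 0.10) rose with salt in the presence of LPS, and their interactions passed in limma (1.79, 1.61, 1.10 and 1.17). Neutrophil and mast cell markers had lower medians in the same comparisons. The mast cell list did not pass with an estimated correlation (camera adjusted p = 0.14 without LPS and 0.33 with LPS).

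A hypothesis was that solute carrier genes are called more often than other genes in the salt comparisons. Of 187 tested, 97 were called without LPS (49 higher, 48 lower), 51.9% against 44.1% of the other genes, an odds ratio of 1.37 (95% interval 1.01 to 1.84, Fisher's exact two-sided p = 0.0374, Benjamini-Hochberg adjusted over both tests 0.0374). With LPS, 92 were called (52 higher, 40 lower), 49.2% against 38.5%, an odds ratio of 1.55 (1.15 to 2.09, Fisher's exact p = 0.00309, adjusted 0.00618). Without the 15 that are in the fixed lists, the odds ratios were 1.31 (Fisher's exact p = 0.0877) and 1.49 (Fisher's exact p = 0.011). Among 10000 random lists matched on expression, the counts stood at percentiles 97.6 and 99.8. Genes are not independent, so these p-values may be too small for the odds ratios of 1.37 and 1.55.

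Camera called 6 of the 25 gene lists in 0 of the 5 comparisons: ER stress, p53 targets and apoptosis, MHC class II presentation, antigen uptake receptors, LXR and PPARG lipid handling, and amino acid transport. For MHC class II presentation the median change was 0.03 for salt without LPS and -0.03 with LPS. Camera compares a list with other genes, so a list not called can still hold changed genes. With LPS at 290 mOsm, 12 of 19 ER stress genes fell and 1 rose (median -0.47). For MHC class II presentation 9 of 13 fell and 2 rose, and for LXR and PPARG lipid handling 12 of 15 fell and 3 rose. Of the cell type lists, 6 of 12 had fewer than 5 tested genes. The neutrophil and mast cell lists shared 0 genes with other lists, while 7 of 14 dendritic cell, 7 of 14 macrophage, 1 of 8 monocyte and 1 of 6 plasmacytoid dendritic cell markers were in another list. Pathway lists overlapped as well. Ifit1, Irf7 and Rsad2 are in both interferon lists, Cxcl9 and Cxcl10 in the type I interferon and chemokine lists, and Sod2 in the NF-kB and oxidative stress lists.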
